A study of Mus musculus with 6 samples.

How the data were processed

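Total RNA of sorted mouse cells was labelled with Cy3 and hybridised to 6 Agilent 1-colour arrays, 3 of cells infected with a control retrovirus and 3 of cells infected with a retrovirus that carries Ebf1. Sample groups and replicate numbers were taken from the sample titles, which name the insert Ebf1beta. Each array file holds 45018 features, of which 1639 are control features. The values used are spot intensities on a linear scale: per the file headers, they were extracted with Agilent Feature Extraction 10.5.1.1 under a 1-colour protocol that subtracts background and removes spatial trends within an array, and no normalisation between arrays is recorded. The submitters' processing notes name Agilent Feature Extraction without a version. The series also holds a deposited table of intensities, which equalled the processed signal of the same array within 0.1 percent at all 45018 features. Its column medians were 13.1, 7.62 and 9.07 for control replicates 1 to 3, and 12.7, 12.3 and 19.7 for Ebf1 replicates 1 to 3. It holds linear signals that were neither centred nor turned into ratios, so using it in place of the array files changed nothing. Probe positions are those of mm9, the genome annotation named in the file headers.

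The log2 of the processed signal was taken and each array's 75th percentile over the 43379 non-control features was subtracted. Spots that the scanner software flagged as outliers, 65 to 116 per array, were left out. Spots of one probe were averaged (245 probes lay on more than 1 spot), which gave 41174 probes. No non-control spot was saturated. A probe was tested when it was well above background, by the software's own flag, on all 3 arrays of at least 1 group. This kept 20455 probes and left out 20719, and 8 of those tested lacked a value on at least 1 array. Gene symbols were updated through the probe's RefSeq accession with a table for assembly GRCm38.p6, from which no coordinates were used. The accessions of 25097 probes (61% of the probes) matched, and 3505 of these had another symbol on the array. Other probes kept the array's name. A gene was represented by its tested probe with the highest mean over the 6 arrays, which gave 13837 genes or unnamed sequences, 4840 of them with several tested probes.

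Groups were compared with the linear model and moderated test of limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with the data.table package (1.17.8), two-sided, with Benjamini-Hochberg adjustment over the tested probes and a threshold of 0.05. All log2 changes are Ebf1 virus minus control virus and are given with the standard error (SE) of that fit. Where a probe was not well above background on any array of one group, the change is given as "at least N-fold". For this bound, the mean of the brighter group was set against the mean of the dimmer group, in which each array's value was raised to that array's lowest signal among probes well above background. The fitted log2 changes of such genes are not sizes, and their order has no meaning. The bounds hold for the processed signal alone: normexp correction adds an offset to every signal, and its log2 changes, given beside them, can lie under them.

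Before the data were examined, 26 gene lists with 573 distinct genes were fixed from general knowledge of blood cell development and cell biology, and 572 of these genes were on the array. The genes of a list that are counted as measured are the members that passed the filter and were tested. They were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with camera at an estimated correlation and with fry. The comparison, the filter, the alternatives and the rule for naming genes were fixed at the same time. The rule names Ebf1, the 12 largest rises and 12 largest falls in fitted log2 change among called genes with a real symbol whose groups did not overlap and which were well above background on all 3 arrays of the higher group, and up to 3 called members of each list with the smallest p. A list with no called member is represented by 1 member, with its values only. This gave 90 genes, not all of which are described in the text. Genes outside the rule are marked in the text as chosen after their values were seen.

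The alternatives were normexp background correction (offset 50), quantile normalisation, median scaling, no filter on dim probes, a filter asking for signal above background on all 6 arrays, the replicate number as a block, the slide as a fixed or random block, eBayes with trend and robust options, treat against a fold of 1.5, the mean of all probes of a gene, the 2 other list tests, the deposited table and leaving out each array in turn. Removal of a trend on probe GC content, and the slide block in the list test, were added after the data had been seen. The fit was tested on simulated data with the spread of this comparison over 20447 probes. It recovered 2% of 50 probes changed by 0.5 on the log2 scale, 46% of those changed by 1, and 100% of those changed by 2 or by 4, with 3.88% false calls among all calls. Only 50 probes were changed at each size, whereas 4435 probes were called in the real comparison. As the adjustment depends on how many probes change, the recovered shares are not the sensitivity of the real comparison. On 13833 simulated genes, the list shifted by 0.7 was called and 0 of 19 unshifted lists were. The simulated genes varied independently of each other. This result therefore gives no error rate for the real lists, whose estimated correlations reached 0.401. Figures were drawn with matplotlib 3.10.9.

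The labels do not say whether the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision. The files place the arrays on 3 slides. Slide 1 held control replicate 2 and Ebf1 replicate 1, slide 2 held control replicates 1 and 3, and slide 3 held Ebf1 replicates 2 and 3. With slide as a fixed block the comparison therefore rests on a single pair of arrays. A genome sequence and gene models were not used here, so exon and untranslated region positions of the probes were not analysed here.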

Results

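Gene expression was compared between mouse pre-pro-B cells lacking Ebf1 that were given the gene back and cells that were not. Ebf1 is a transcription factor needed for commitment to the B cell lineage, and pre-pro-B cells are the stage at which development stops without it. The cells were kept on OP9 stromal feeder cells with interleukin 7, stem cell factor and Flt3 ligand at 10 ng/ml each. They were infected either with a retrovirus encoding EGFP alone (control, n = 3) or with one encoding Ebf1 and EGFP (n = 3), and EGFP-positive cells were sorted 24 h later. The 75th percentile signal was 240 to 366 on the control arrays and 316 to 364 on the Ebf1 arrays. Between 46.3% and 50.2% of probes were well above background on control arrays, and between 50.4% and 59.8% on Ebf1 arrays.

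The comparison addresses which genes respond within 24 h of restoring Ebf1. Transcripts of the surrogate light chain, which pairs with the heavy chain in the pre-B cell receptor, were among the steepest rises. Igll1 (lambda 5, probe on chromosome 16, 16861104 to 16861163, mm9) went from -4.56 ± 0.11 in control cells to 6.44 ± 0.11 in Ebf1 cells (mean log2 signal relative to the 75th percentile ± SD, n = 3 arrays each). This is a log2 change of 11.00 ± 0.14 (SE, limma adjusted p = 5.87e-08) or 2046-fold, with 2 of the 3 control arrays above background, and 8.65 with normexp correction. Vpreb1 (chromosome 16, 16868559 to 16868618) rose from 0.43 ± 0.14 to 8.63 ± 0.11, which is 294-fold (log2 change 8.20 ± 0.15, adjusted p = 3.48e-07). Vpreb2 rose by 9.04 ± 0.27 (6.34 with normexp correction), with 1 of 3 control arrays above background. Cd79b, a signalling chain of the B cell receptor (chromosome 11, 106172780 to 106172839), rose from -1.94 ± 0.12 to 5.48 ± 0.15, which is 171-fold. With slide as a block these changes were 11.09 for Igll1, 7.97 for Vpreb1 and 7.71 for Cd79b, and with normexp correction Cd79b was at 6.58. Chosen after its value was seen, the mu heavy chain constant region, listed on the array as Igh-6, was the tested member that did not pass, at a log2 change of 0.07 ± 0.14. Of the 6 tested pre-B receptor components 5 rose and 0 fell, the same count when adjusted over the list alone. Cd79a, the other of the 7 members on the array, did not pass the filter on signal above background and was not tested. The list had a median log2 change of 7.81 and a camera adjusted p of 1.86e-07 (4.46e-07 with slide as a block). With an estimated correlation its adjusted p was 0.113.

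**Figure D1:**
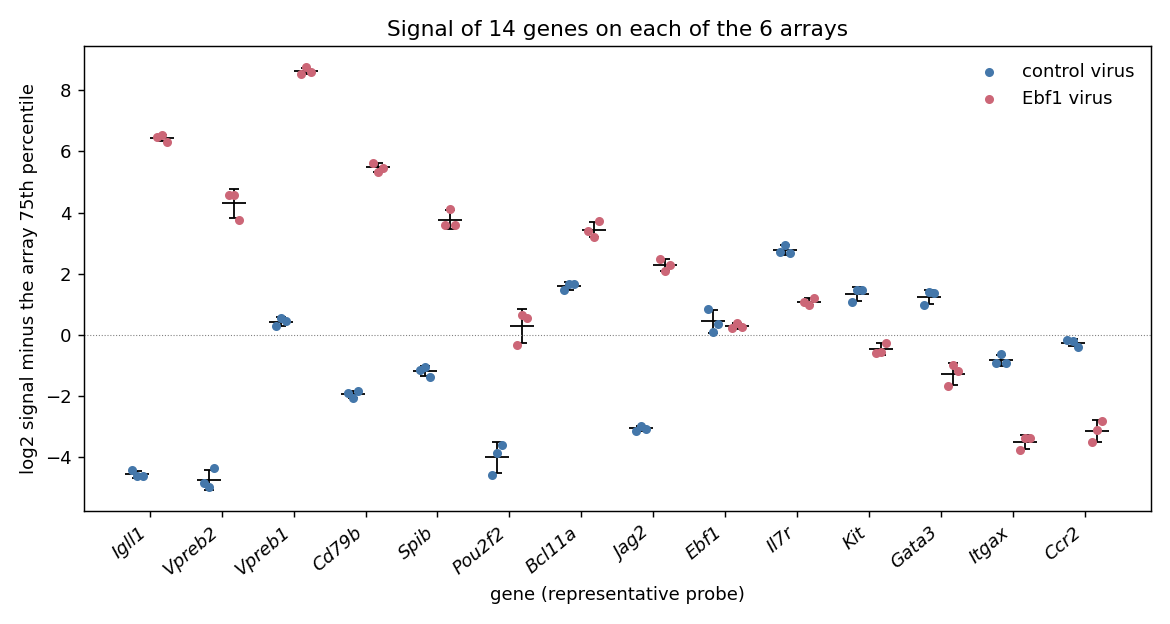
Log2 signal minus the array's 75th percentile (vertical axis) of 14 genes on each of the 3 control arrays and 3 Ebf1 arrays; points are arrays, and the black marks are the mean ± SD of a group. Igll1 lies near -4.56 in control and 6.44 in Ebf1 cells, Il7r near 2.77 and 1.08, and the Ebf1 probe overlaps between groups.

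For Ebf1 itself, 1 probe was above background (chromosome 11, 44818365 to 44818424), at 0.44 ± 0.39 in control and 0.29 ± 0.09 in Ebf1 cells (SD, n = 3). Its log2 change of -0.15 ± 0.21 did not pass the test (limma adjusted p = 0.646). The cells are labelled Ebf1 -/-, yet this probe was well above background on all 3 control arrays. What it reads there was not tested, so its signal does not show an intact Ebf1 transcript. A second Ebf1 probe was not well above background on any array. Whether either probe lies in the part of the transcript carried by the virus is not known here, so these values check nothing about the sample labels.

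Transcription factors of the B lineage rose more often than they fell. Of the 22 on the array, Pax5 did not pass the filter on signal above background and was not tested. Among the 21 tested, 9 rose and 2 fell (11 and 2 when adjusted over the list alone), with a median log2 change of 0.47 and a camera adjusted p of 0.0114 (0.0354 with slide as a block). With an estimated correlation the adjusted p was 0.358. Spib, an Ets family factor of B cells and plasmacytoid dendritic cells, rose by 4.95 ± 0.20 on the log2 scale. Pou2f2, which encodes the octamer-binding protein Oct-2, rose by 4.30 ± 0.34 (2.24 with normexp correction), with 2 of 3 control arrays above background, and Bcl11a rose by 1.85 ± 0.17. Chosen after their values were seen, Foxo1 rose by 1.30 ± 0.19, Pou2af1, the Oct-2 coactivator, was at least 4.27-fold higher (log2 change 0.93 with normexp correction), and Runx1 and Lef1 fell by 1.65 and 1.14 (Runx1 stayed called at a smaller size with normexp correction). Of 26 genes of B cell receptor signalling 6 rose and 1 fell (7 and 2 over the list alone), with a camera adjusted p of 0.0803 for the list. Over the alternatives with camera at its preset correlation that p ran from 0.00129 to 0.258, and it passed with normexp correction, without a filter, with the filter on all 6 arrays and with the mean of all probes of a gene, as it did in fry (0.014). Cd72, an inhibitory coreceptor, rose by 2.00 ± 0.17 on the log2 scale, whereas Rasgrp3 was at least 4.97-fold lower (log2 change -0.60 with normexp correction). Later B cell surface markers were divided: of 12 measured 4 rose and 4 fell (5 and 4 over the list alone), and the list did not pass (camera adjusted p = 0.817). Its median log2 change was 0.33 but its mean was 0.76. Chosen after their values were seen, Ms4a1 and Cd40 were higher, at log2 changes of 4.41 and 0.61 with normexp correction (limma adjusted p = 1.36e-08 and 0.03). Bst1 was at least 1.78-fold higher but lost its call with normexp correction (log2 change 0.43), while Il2ra, the interleukin 2 receptor alpha chain, fell by 2.47 ± 0.23 and Cxcr5 by 1.60 ± 0.17. With normexp correction Il2ra was at -1.53.

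Genes of the progenitor state and of other lineages moved in both directions. The interleukin 7 receptor gene Il7r fell by 1.69 ± 0.15 on the log2 scale (limma adjusted p = 0.000196) and the survival gene Bcl2 by 1.54 ± 0.18, while Stat5a, which acts downstream of the receptor, rose by 1.66 ± 0.26 (2.38 with slide as a block). Of the 17 genes of this pathway 3 rose and 4 fell (5 and 4 over the list alone), with a median of 0.04, a mean of -0.06 and a camera adjusted p of 0.884. Among 21 stem and multipotent progenitor genes 4 rose and 8 fell (5 and 9 over the list alone, camera adjusted p = 0.194, fry adjusted p = 0.00811). Kit, the stem cell factor receptor, fell by 1.82 ± 0.18, Tal1 by 1.76 ± 0.16 and Mycn by 1.68 ± 0.16. Of 18 T cell markers 1 rose and 7 fell (2 and 7 over the list alone, camera adjusted p = 0.0737). Over the alternatives with camera at its preset correlation that p ran from 0.036 to 0.625. It passed with median scaling, with the mean of all probes, with GC content removed, without control replicate 2 (0.0419) and in fry (0.0145). Gata3, a factor of the T and innate lymphoid lineages, fell by 2.53 ± 0.22, Txk by 2.07 ± 0.23 and Trat1 by 1.91 ± 0.18. Of 13 natural killer and innate lymphoid markers 3 rose and 4 fell (4 and 6 over the list alone, camera adjusted p = 0.837), with a median of -0.33 but a mean of 0.15. The protease gene Gzma rose by 5.36 ± 0.16 and Tbx21, encoding T-bet, by 3.55 ± 0.22 (2.10 with normexp correction), while Il2rb fell by 2.19 ± 0.14.

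Of 15 myeloid markers 4 rose and 7 fell, the same count over the list alone (camera adjusted p = 0.837). Gfi1 fell by 1.24 ± 0.15 and the Fc receptor gene Fcgr1 by 2.29 ± 0.28, and Prtn3 rose by 1.43 ± 0.17. With normexp correction Fcgr1 was at -1.04, and Prtn3, at 0.41, lost its call. Of 11 dendritic cell markers 2 rose and 4 fell (4 and 5 over the list alone, camera adjusted p = 0.817, fry adjusted p = 0.0458). Itgax, which encodes CD11c, fell by 2.69 ± 0.18 and Ccr9 by 2.50 ± 0.26, while Ly6d, which also marks B cell progenitors, rose by 2.62 ± 0.19. With normexp correction Itgax was at -1.29. Of 5 mast cell and basophil markers 2 rose and 2 fell, the same over the list alone (camera adjusted p = 0.983), with Gata2 at least 2.63-fold and Hdc at least 1.24-fold higher and Kit lower as above. With normexp correction Gata2 (log2 change 0.38) and Hdc (0.10) lost their calls, and Hdc also lost it with quantile normalisation, median scaling and the slide block. Among 11 tested erythroid and megakaryocyte markers, of 20 on the array, 6 rose and 3 fell, the same over the list alone. Their median was 1.48, or 0.89 with the 3 members that were dim in a group at their bounds. It was 0.26 with normexp correction and 0.34 without a filter on dim probes, against 1.23 with quantile normalisation and 1.17 with median scaling. The camera adjusted p was 0.0282 and, with an estimated correlation, the adjusted p was 0.435. Zfpm1, which encodes the GATA cofactor FOG-1, rose by 2.48 ± 0.20 and Nfe2 by 1.63 ± 0.14, and Alas2 was at least 2.50-fold higher (log2 change 0.56 with normexp correction). Over the alternatives with camera at its preset correlation this list's adjusted p ran from 0.0167 to 0.295, and its call was lost with normexp correction, quantile normalisation, the filter on all 6 arrays, the replicate block and the slide block (0.0755).

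Of 15 measured genes of the Notch pathway, which directs lymphoid progenitors to the T cell fate, 8 rose, 1 fell and 6 did not pass the test (8 and 2 over the list alone), with a median log2 change of 0.47 and a camera adjusted p of 0.0108. With an estimated correlation the adjusted p was 0.358. Over the alternatives at the preset correlation it ran from 4.71e-05 to 0.073, the highest with slide as a block, and the call was also lost with the filter on all 6 arrays. The ligand gene Jag2 rose by 5.36 ± 0.15 and Dtx1 by 3.49 ± 0.25, and the ligand gene Dll4 was at least 3.14-fold higher. Chosen after their values were seen, the receptor gene Notch1 rose by 2.01 ± 0.15 and the target gene Hes1 was at least 4.57-fold higher, while Il2ra was the member that fell. With normexp correction the log2 changes were 4.06 for Jag2, 2.41 for Dtx1, 0.64 for Dll4 and 0.91 for Hes1.

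Of 24 measured chemokine receptors and adhesion molecules 4 rose and 11 fell (5 and 12 over the list alone), with a median of -0.48. The camera adjusted p was 0.0494, and with an estimated correlation the adjusted p was 0.358. Ccr2 fell by 2.89 ± 0.20 and Ccr9 by 2.50 ± 0.26, and Cxcr3 rose by 2.22 ± 0.20, against -1.65 for Ccr2 and 1.51 for Cxcr3 with normexp correction. Over the alternatives with camera at its preset correlation the list's p ran from 0.0212 to 0.142. The call was lost with quantile normalisation, median scaling, no filter, the replicate block and the slide block (0.142). It was also lost without control replicate 1 (0.0873), 2 (0.0581) or 3 (0.0683) and without Ebf1 replicate 3 (0.0616).

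Of 26 ribosome biogenesis genes 17 fell and 0 rose (20 and 0 over the list alone). Their median log2 change was -0.68 and the camera adjusted p was 1.86e-07 (5.94e-06 with slide as a block). With an estimated correlation the adjusted p was 0.358. Grwd1 fell by 1.04 ± 0.13, Nop2 by 1.00 ± 0.15 and Nolc1 by 0.98 ± 0.16. Of 22 cholesterol synthesis genes 2 rose and 6 fell (2 and 12 over the list alone), with a median of -0.44 and a camera adjusted p of 0.0167. With an estimated correlation the adjusted p was 0.435. At the preset correlation it ran from 0.00758 to 0.16 over the alternatives, and the call was lost with quantile normalisation, median scaling and the slide block (0.142). Sc5d fell by 0.79 ± 0.16 and Cyp51, with 1 of 3 probes called, by 0.69 ± 0.14, while Mvk rose by 1.23 ± 0.15. The 27 S phase genes shifted down by a median of -0.31 (camera adjusted p = 0.0167, adjusted p = 0.435 with an estimated correlation). At the preset correlation that p ran from 0.00946 to 0.16 over the alternatives, and the call was lost with quantile normalisation, median scaling and the slide block (0.0755). Only Ccne1, which fell by 1.13 ± 0.16, and Uhrf1, which rose by 0.72 ± 0.18, passed the test, and 0 rose and 1 fell over the list alone. The 24 genes of oxidative phosphorylation had a median of -0.29 (camera adjusted p = 0.0494, adjusted p = 0.511 with an estimated correlation), with 0 called in limma's test over all genes or adjusted over the list alone. Uqcrq, the member with the smallest p, was at -0.46 ± 0.14 (adjusted p = 0.0541). At the preset correlation this list's p ran from 0.0409 to 0.386 over the alternatives. Its call was lost with normexp correction, quantile normalisation, median scaling, no filter, the filter on all 6 arrays, either block as a fixed term and the mean of all probes. It was also lost without control replicate 1 (0.0772) or 3 (0.0985) and without Ebf1 replicate 1 (0.0649) or 3 (0.0604). Of 28 G2/M phase genes 0 were called by limma either way, and the list's median was 0.01 (camera adjusted p = 0.837). Ccnb2 had the smallest p there, at 0.42 ± 0.14 (adjusted p = 0.0677).

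Markers of the stromal feeder cells were also higher in the Ebf1 samples. Of 19 measured 3 rose and 0 fell (6 and 0 over the list alone), with a median of 0.57 and a camera adjusted p of 0.0024 (0.0354 with slide as a block). With an estimated correlation the adjusted p was 0.52. Fn1 (fibronectin), with 1 of 2 probes called, rose by 1.07 ± 0.30, Col5a1 by 0.88 ± 0.26 and Fstl1 by 0.65 ± 0.17. At camera's preset correlation the list's p ran from 3.94e-05 to 0.105 over the alternatives, the highest with median scaling, with which the list and these 3 genes lost their calls. In fry the list did not pass (0.0669). The 3 genes also lost them without single arrays, as given for all named genes at the end.

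The remaining lists did not pass camera's threshold. Of 21 interferon response genes 5 rose and 3 fell, the same over the list alone, with a median of 0.00, a mean of 0.24 and an adjusted p of 0.817. Isg15 rose by 1.89 ± 0.21 and Mx2 by 1.18 ± 0.15, and Oasl2, with 2 of 3 Ebf1 arrays above background, fell by 2.39 ± 0.30 (-0.92 with normexp correction). Of 27 p53 and apoptosis genes 4 rose and 2 fell, the same over the list alone (adjusted p = 0.837), with Bmf up by 1.60 ± 0.22 and Perp down by a log2 change of -1.81 ± 0.20. Of 21 immediate early and heat shock genes 2 rose and 2 fell, the same over the list alone (adjusted p = 0.845). Dusp2 rose by 1.25 ± 0.15, Klf4 by 1.48 ± 0.22 (0.88 and not called with slide as a block), and Dnajb1, with 1 of 2 probes called, fell by 0.66 ± 0.14. Of 20 unfolded protein response genes 3 rose and 1 fell, the same over the list alone (adjusted p = 0.845), with Ddit3 at 0.99 ± 0.15, Atf5 at 1.04 ± 0.16 and Asns at -0.69 ± 0.14. Of 20 glycolysis genes 1 rose and 0 fell, also over the list alone (adjusted p = 0.845), and it was Pfkfb3, at 0.72 ± 0.14. Of 11 genes of V(D)J recombination, the joining of antigen receptor gene segments, 1 rose and 3 fell (2 and 4 over the list alone, adjusted p = 0.817), with Rag1 (2 of 3 probes called) at 0.86 ± 0.18, Lig4 (1 of 2) at -0.73 ± 0.13 and Polm at -0.79 ± 0.16.

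**Figure D2:**
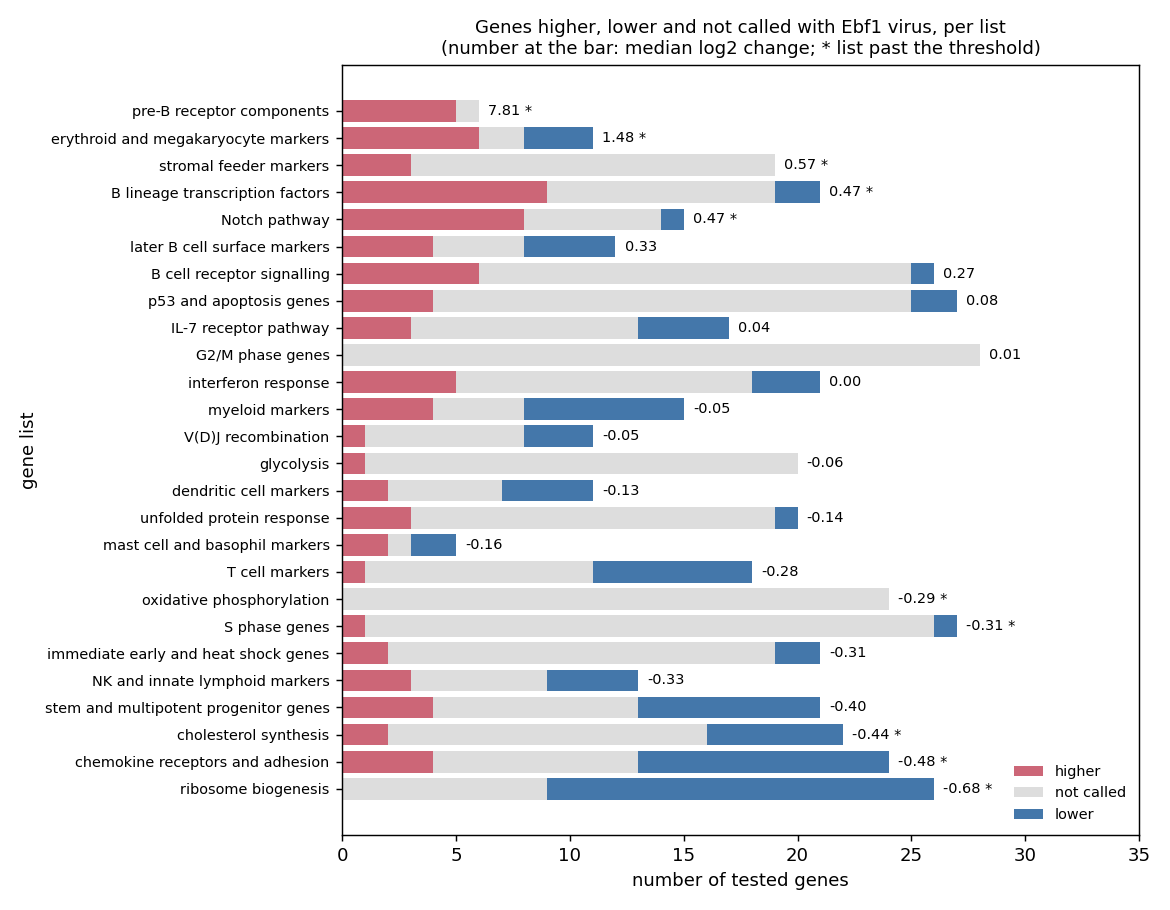
Number of tested genes (horizontal axis) called higher, not called and called lower in Ebf1 cells for each of the 26 gene lists, ordered by their median log2 change, which is printed at the bar; an asterisk marks camera adjusted p under 0.05. Ribosome biogenesis has 17 of 26 members lower and pre-B receptor components have 5 of 6 higher, and 10 lists carry the asterisk.

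The other largest fitted rises included genes known from other tissues. Col26a1 (a collagen, Emid2 on the array) was at least 799-fold higher, Ppl (periplakin of epithelial junctions) at least 195-fold, Gcgr (the glucagon receptor) at least 120-fold and Tnnt2 (cardiac troponin T) at least 106-fold. Cidea, a lipid droplet protein gene, was at least 94.1-fold higher, Ell3 at least 84.9-fold, Foxo6 at least 74.6-fold and Gng13 at least 64.5-fold. These 8 genes were not well above background on any control array. With normexp correction all 8 stayed called, at smaller log2 changes of 7.05 for Col26a1, 5.12 for Ppl, 4.64 for Gcgr, 4.50 for Tnnt2, 4.10 for Cidea, 4.00 for Ell3, 3.74 for Foxo6 and 3.82 for Gng13. A second Tnnt2 probe, not tested, was above background on 0 of the 6 arrays. Ndrg4 also rose, with 1 of 3 control arrays above background, so that its size is uncertain (log2 changes of 5.20 to 8.26 over the alternatives). The largest fitted falls included 4 genes whose representative probe was not well above background on any Ebf1 array, so that their rank has no meaning. Akap4, a sperm tail protein gene, was at least 14.5-fold lower, Calm5 at least 6.32-fold, Prok1 at least 2.98-fold and the olfactory receptor gene Olfr19 at least 2.47-fold. The Akap4 bound is one of group means: its control replicates 1 to 3 lay at -0.61, -0.25 and -3.17, and replicate 3 alone would give a smaller bound. With normexp correction Akap4 was at -1.70 and Calm5 at -0.80, and Prok1 (-0.42) and Olfr19 (-0.40) lost their calls. A second Prok1 probe, not tested, was above background on 2 Ebf1 arrays and 0 control arrays. Hs3st1, a heparan sulfate sulfotransferase gene, fell by 3.75 ± 0.21 and the potassium channel subunit gene Kcne3 by 3.19 ± 0.19, each with 1 of 3 Ebf1 arrays above background, so that these sizes are uncertain, with changes of -1.21 and -1.06 under normexp correction. Filip1 fell by 3.12 ± 0.28, Kcnj1 by 2.97 ± 0.19 and Ntng1 by 2.95 ± 0.50 (-1.77, -1.71 and -1.42 with normexp correction). Heavy chain variable region probes named Igh and Igh-VJ558 fell by 2.94 ± 0.23 and 2.86 ± 0.21. They belong to a multigene family with shared sequence, so which member they read is uncertain, and 4 of 5 tested Igh probes and 6 of 6 Igh-VJ558 probes were called lower.

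Between arrays, correlations followed the virus. Pearson correlations across the tested probes were 0.989 to 0.993 between control arrays, 0.984 to 0.992 between Ebf1 arrays, and 0.938 to 0.958 between groups. The first principal component held 74.3% of the variance and placed the control arrays between -65.8 and -62.3 and the Ebf1 arrays between 57.9 and 72.8. Across the array, limma called 3263 of 13837 genes (23.6%), 1739 higher and 1524 lower in Ebf1 cells. By probe it called 4435 of 20455, 2350 higher and 2085 lower, and 2101 of them changed at least 2-fold, 1411 higher and 690 lower. By gene 1575 passed both limits, 1056 higher and 519 lower. Of the 1056, 322 were not well above background on any control array, and 205 of these were bounded at 2-fold or more. The 3 values of one group all lay on one side of the other group's for 6287 genes (45.5%), where chance gives 10%. With median scaling the median log2 change of the tested probes was -0.37 instead of -0.06, and directions are relative to that shift: higher probes made up 32.2% of the calls instead of 53%, and 37.4% of those of at least 2-fold instead of 67.2%. Higher probes were also the smaller part of the calls with normexp correction (45.9%), the filter on all 6 arrays (44.6%) and eBayes with trend and robust options (47.8%). Of the 26 lists 10 passed camera's threshold (12 at an unadjusted p under 0.05), 5 up and 5 down, and with an estimated correlation 0 passed (2 unadjusted). Fry, which does not compare a list with other genes, passed 13.

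With slide as a fixed block, 1502 genes (889 higher, 613 lower), 2168 probes and 4 lists were called. All 3263 called genes had the same sign between the 2 arrays of opposite groups on slide 1, which are themselves part of the comparison. Without control replicate 2 the count of genes was 1951, and without control replicate 3 it was 2152. Lower genes numbered 739 and 818 in these fits and 923 without Ebf1 replicate 2. Without a filter on dim probes 1547 genes were called, and with normexp correction 1020 probes changed at least 2-fold, against 1382 with the filter on all 6 arrays. Of the 87 called genes named by the rule, 20 lost their call with slide as a block: Asns, Col5a1, Cyp51, Ddit3, Dnajb1, Fstl1, Gfi1, Hdc, Klf4, Lig4, Mvk, Mx2, Nolc1, Nop2, Pfkfb3, Polm, Prtn3, Rag1, Sc5d and Uhrf1. With median scaling 10 did: Atf5, Col5a1, Ddit3, Fn1, Fstl1, Hdc, Mx2, Pfkfb3, Rag1 and Uhrf1. On leaving out 1 array 9 lost it, at adjusted p from 0.0521 to 0.15. Col5a1 lost it without any array, Fn1 without any but Ebf1 replicate 3, Fstl1 without any but control replicate 2, and Uhrf1 without any but Ebf1 replicate 2. Asns and Dnajb1 lost it without control replicate 2 or 3, Cyp51 and Polm without control replicate 2, and Rag1 without control replicate 3.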

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

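The GC content trend and the slide block in the list test were chosen after the data had been seen. No called gene among those named and no called list changed direction in the alternatives run for it, but the balance of all calls did, as given in the report, and the uncalled Ebf1 change was 0.11 with the slide block against -0.15. Treat and the mean of all probes were not run for single named genes, and 26 of these were not tested under the filter on all 6 arrays. Of the 87 called named genes 61 kept their call in the alternatives run for them, omissions of an array included, and 26 lost it in at least 1, with Col5a1, Fstl1, Fn1 and Uhrf1 the most often affected. The cause was not tested except where the construction gives it. Genes near background limit the folds, since 338 of the 1739 higher genes had no control array above background.

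With normexp correction, whose offset compresses low signals, 1020 probes changed at least 2-fold (678 higher, 342 lower), 6 named genes (Bst1, Gata2, Hdc, Olfr19, Prok1 and Prtn3) lost their call, and the mean correlation between groups was 0.969 instead of 0.951. Quantile normalisation left 5 lists. Median scaling gave 1256 higher probes, 957 higher genes, 1845 lower probes of at least 2-fold and 6 lists. The shift of all genes given in the report moves the counts by direction, and the cause of the loss of lists was not tested. Without a filter 41174 probes were tested and 1996 called (1341 higher, 655 lower), as were 1547 genes (1030 higher, 517 lower), with a similarity of 0.970. The filter on all 6 arrays removed genes silent in one group and left 1382 probes of at least 2-fold, 775 of them higher, with a similarity of 0.966. Treat at 1.5-fold called 1362 probes, 1011 higher and 351 lower. Camera with an estimated correlation passed 0 lists. GC correction called 3410 genes, 3079 of them shared with the 3263.

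The slide block called 2168 probes (1270 higher, 898 lower), 1502 genes (889 higher, 613 lower) and 4 lists, and 1274 of the genes were among the 3263. It rests on 1 pair of arrays. Slide as a random block (consensus correlation 0.0106) called 3246 genes. The replicate numbers did not pair the arrays: the deviations of same-numbered arrays from their group means correlated at -0.17, -0.25 and 0.095. For control replicate 2 and Ebf1 replicate 1, which shared a slide, that correlation was 0.29, the highest between arrays of opposite groups. The replicate block called 2306 genes, 925 of them lower, and 1233 lower probes.

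Leaving out 1 array at a time gave 2610 to 3702 probes (1594 to 2124 higher, 1016 to 1687 lower), 1951 to 2730 genes (1212 to 1563 higher, 739 to 1221 lower), 1996 to 2207 probes of at least 2-fold (1324 to 1541 higher, 577 to 820 lower), 8 to 10 lists, a similarity of 0.948 to 0.954 and an Ebf1 change of -0.32 to 0.06. Fewer arrays lower the power. The count of lower genes was 739 without control replicate 2, 818 without control replicate 3 and 923 without Ebf1 replicate 2, against 1524 with all arrays.

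The 10 splits of the 6 arrays are too few for a share under 0.05, the smallest being 0.1. The real split gave 4435 probes, 2101 probes of at least 2-fold, 3263 genes and 10 lists, and in each case 1 split, the real one, gave as many. The highest of the other 9 was 0 probes, 0 probes of at least 2-fold, 0 genes and 3 lists. Each of these 9 mixes the virus groups, so the difference between the groups enters the spread, and their 0 calls give no rate of false calls.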

Other observations

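The tests of striated muscle and epithelial genes, of feeder cell carry-over, of the heavy chain probes without Zfp386, of array brightness on genes chosen without the arrays compared, of array brightness and signal distribution as the cause of a whole pattern, of the groups within slides, of muscle and junction genes by their other probes and of neighbours among accession-matched genes were chosen after the result was seen, as were the genes and regions named here. Striated muscle genes were among the transcripts that appeared with Ebf1. Ckm, the muscle creatine kinase gene, was at least 36.7-fold higher, Mybpc2 at least 13.3-fold, Trim63 at least 13.4-fold and Myh6 at least 8.86-fold. With normexp correction, whose offset compresses low signals, the log2 changes were 2.88 for Ckm, 1.76 for Mybpc2, 1.81 for Trim63 and 1.26 for Myh6. Muscle genes already above background went both ways: Myl4 rose by 3.01 ± 0.17 and Mylk2 by 2.52 ± 0.24 on the log2 scale, while Actn2 fell by 1.53 ± 0.27 and Cox6a2 by 1.76 ± 0.14 (1.15 for Mylk2 and -0.66 for Actn2 with normexp correction). Epithelial junction genes did likewise. Evpl (envoplakin) rose by 7.96 ± 0.19 and Jup (plakoglobin), with 1 of 3 control arrays above background, by 2.32 ± 0.26, Pkp1 was at least 14.9-fold higher, and Perp fell by 1.81 ± 0.20. With normexp correction Evpl was at 6.87, Jup at 0.66 and Pkp1 at 1.78.

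A muscle list and an epithelial junction list drawn up after the largest rises were seen were compared with all other genes or unnamed sequences whose every probe was not well above background on any control array. Whether unnamed sequences rise at another rate than named genes was not tested. Of 30 such muscle genes 9 rose (30%), against 315 of 13492 others (2.33%; Fisher's exact test, two-sided, p = 2.14e-08). Without Tnnt2, which prompted the list, it was 8 of 29 (exact p = 2.29e-07). The rises of Myh4, Myh8 and Tnnt2 rest on 1 probe each, their other probes being above background on 0 Ebf1 arrays. With risen genes of this kind left out of both groups it was 6 of 27 (exact p = 1.9e-05). Fisher's test takes genes as independent, but related or neighbouring genes can rise together, so these p-values can be too small. With normexp correction Xirp1, 1 of the 9, lost its call (log2 change 0.29) and the others kept theirs. Of 26 such junction genes 3 rose (exact p = 0.0236), but without Ppl, which prompted that list, it was 2 of 25 (exact p = 0.115). Cdh1, 1 of the 3, lost its call with normexp correction (log2 change 0.43). The hypothesis that silent muscle genes respond to Ebf1 more often than other silent genes may be followed up on other data, and the one on junction genes rests on Ppl.

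Called genes also lay side by side on the chromosomes more often than shuffled calls did. With the Igh variable region left out, 465 adjacent pairs of genes both rose, where the median of 10000 shuffles was 218 and the highest 285. For falls there were 290 pairs, against a median of 160 and a highest of 201. Some of these are 1 transcript under 2 names. Among the 10338 genes matched by accession there were 328 pairs that rose (median 177) and 209 that fell (median 141), each with a one-sided p of 1e-04, the smallest the shuffles can give. One run on chromosome 1 (137747976 to 138074549, mm9) held Tnnt2, Pkp1, Tmem9, Cacna1s and Kif21b, all higher, so some muscle and junction genes were neighbours. A second Cacna1s probe, not tested, was above background on 2 control arrays and 0 Ebf1 arrays. Another on chromosome 11 (106124810 to 106180780) held Smarcd2, Gh, Cd79b, the muscle sodium channel gene Scn4a and an unnamed sequence, all higher. On chromosome 13 (3650835 to 3853972) Asb13, Calml3, Calm4 and Calm5 all fell. A spread of Ebf1's effect to neighbours is a candidate explanation, but duplicated genes with similar probes and clusters of genes of like expression remain open, as the shuffles keep neither.

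The first pattern weighed is the rise of 322 genes not well above background on any control array. A GC content trend shared by all tested probes was argued against, since 100% stayed called and at least 2-fold higher after it was removed. The trend was fitted over all tested probes, where the Pearson correlation of log2 change with GC percent was 0.083. A GC effect limited to dim probes was therefore not tested. Array brightness as the whole cause was argued against: between control replicate 1 and Ebf1 replicates 1 and 2, arrays of like 75th percentile signal, genes chosen on the other 4 arrays had median log2 changes of 2.70 and 2.60, though in the latter pair the share at least 2-fold higher was 79.3%, short of the 80% set (92.5% of the 322, which that pair had helped to choose). A difference in signal distribution was argued against as the whole cause by the median of 2.94 with quantile normalisation (3.02 before), but 86% stayed, short of the 90% set beforehand. It remains open for the other 45, whose median went from 1.33 (median SE 0.29) to 0.96 (0.35), with 28 under 2-fold and 34 not called. These 45 are the genes that did not stay, so their drop follows from the choice and is no further evidence. Stray binding of single probes remains open: 37.4% of 139 other probes of these genes were at least 2-fold higher, against 5.97% of other probes of all tested genes, which lies between the bounds set. An effect of Ebf1 is the biological explanation that the design gives, and it may hold for genes that several probes bear out.

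The second is the fall of the heavy chain variable region. Of 40 tested probes on chromosome 12 (115298043 to 117238298, mm9) 38 were lower and 0 higher, with a median log2 change of -2.52, while the constant region probe Igh-6 was at 0.07 ± 0.14. Slide was argued against by the median of -2.74, over 42 probes including 2 of Zfp386, between the 2 arrays of opposite groups on slide 1. The mean within slides for the 40, -2.67 ± 0.37 (SE), rests on the same pair of arrays and is not a second comparison. Whether many probes read 1 transcript cannot be told: the set as drawn took in 2 probes of Zfp386, outside the family, and 6 probes sharing no 15-base stretch had a median of -0.363, but without Zfp386 only 4 such probes were left, with a median of -1.62 and 3 of them lower. A loss of 1 abundant rearranged transcript and a fall of many variable region transcripts both remain possible.

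The third is the rise of stromal feeder markers. Carry-over of OP9 cells, which the EGFP sort should remove unless they were infected too, is a candidate explanation, since 18 of 19 markers were above 0, 0 were lower by more than 1 SE, and they varied together between arrays of one group (mean correlation 0.401, the highest of the 26 lists). All 19 were above background on every control array, and 0 belong to another list. Acta2, at 4.43 in control cells, did not rise with them, at -0.02 ± 0.16, while Pdgfrb, at 2.85, was at 0.59 ± 0.21 and Col1a2, at 2.25, at 0.52 ± 0.16. As signal levels of different probes are not comparable and Acta2 is 1 of the 19, this does not decide on carry-over. Slide stays open: the median between the 2 arrays on slide 1 was 0.434, not clearly past the 0.4 set beforehand. The SE over the 19 markers in this 1 pair was 0.115. It is not an error between arrays, and it takes the markers as independent, so it can be too small. Although the list kept its call with slide as a block (camera adjusted p = 0.0354), the markers vary together. Their mean differed by 0.44 ± 0.18 (SE, 2 residual degrees of freedom) within slides, which rests on the same pair of arrays. A response of such genes to Ebf1 was not tested.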
